A study of Homo sapiens with 12 samples.

How the data were processed

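RNA was measured by poly(A) RNA sequencing in 12 libraries of HK-2 cells, a human renal proximal tubule epithelial line that here carried a doxycycline-inducible PRCC-TFE3 fusion gene. PRCC-TFE3 joins the PRCC gene to the transcription factor gene TFE3 and is found in translocation renal cell carcinoma. Cells were kept for 48 h in 4 conditions: vehicle (DMSO), doxycycline (Dox), the CDK8 and CDK19 kinase inhibitor MSC2530818 at 100 nM, and Dox with the inhibitor. CDK8 and CDK19 are the kinases of the Mediator complex, which bridges transcription factors and RNA polymerase II. Each condition had 3 libraries, which the labels describe as independent biological replicates. Per the labels' protocols, total RNA was extracted with TRIzol, its quality was checked on a Bioanalyzer, and libraries were made with a stranded TruSeq mRNA kit. No condition gave Dox to cells without the fusion gene, so effects of the fusion and of Dox itself are confounded.

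The deposited table gives FPKM (fragments scaled by transcript length and by the fragments of the library) for 26334 gene symbols in 12 columns, 1 per library, rounded to 2 decimals. The submitters' processing notes name Trim Galore 0.6.7, Salmon 1.9.0 and the genome builds GRCh38.p13 and hg38, without a role or an order. The gene annotation, the summing of transcripts to genes and the calculation of FPKM are not given in the sources used here. Each column was matched to a sample by its name. The table lists 0 genes with the prefix of mitochondrially encoded genes, so those transcripts were not analysed here. Reads of the introduced fusion transcript cannot be separated from reads of the resident PRCC and TFE3 genes in values summed per gene.

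FPKM sums per library ran from 429208 to 473950, and replicate 1 had the highest sum in each of the 4 groups. Total read counts are not in the table, so absolute depth is unknown and no counting intervals were calculated. Relative depth was estimated from short non-coding genes, whose values within 1.5 times of the smallest were taken as single fragments, and ran from 0.86 to 1.12 of the mean library, on 4 to 25 genes per library. Larger single-fragment values, as a shallower library would give, fall outside this window. The range was thus held near 1 in advance and does not show equal depth. Between 11952 and 12333 genes per library reached an FPKM of 1. Within groups, Pearson r across genes ran from 0.979 to 0.9932, and no pair of libraries was a duplicate (53 to 106 tested genes had identical values).

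Values were analysed as log2(FPKM + 1) without rescaling. A gene was tested when its FPKM reached 1 in at least 3 of the 12 libraries, which kept 12649 genes, 48% of the table. All fold changes are on the log2(FPKM + 1) scale, which understates changes of genes with a low FPKM. One linear model with the 4 groups as means was fitted to all 12 libraries (8 residual degrees of freedom) with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and an intensity trend. The comparisons were Dox against vehicle, Dox against no Dox in the presence of the inhibitor, inhibitor against vehicle, inhibitor against no inhibitor in the presence of Dox, and the interaction, which is the Dox change with the inhibitor minus the Dox change without it. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. All adjusted p-values of genes are two-sided and come from this limma model. Values after ± are SD over 3 libraries for FPKM and SE for log2 changes.

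Gene lists were compiled from general knowledge: fusion partners, Mediator kinase module, MiT/TFE family, translocation RCC markers, lysosomal hydrolases, lysosomal membrane and trafficking, V-ATPase subunits, autophagy, amino acid sensing to mTORC1, NRF2 antioxidant genes, OXPHOS nuclear subunits, mitochondrial DNA-encoded mRNAs, mitochondrial ribosome, TCA cycle, glycolysis, hypoxia response, cholesterol synthesis, fatty acid and triglyceride synthesis, fatty acid oxidation, amino acid response (ATF4), unfolded protein response, G1/S and DNA replication, G2/M and mitosis, CDK inhibitors and p53 targets, interferon response, antigen presentation (MHC class I), NF-kB and inflammatory cytokines, immediate early genes, Wnt/beta-catenin targets, TGF-beta and SMAD targets, mesenchymal and extracellular matrix, epithelial junctions and keratins, proximal tubule, proximal tubule injury, distal tubule and collecting duct, podocyte, endothelial, leukocyte, melanocyte pigment genes, cytosolic ribosomal proteins, replication-dependent histones, angiogenic and growth factors, and heat shock proteins. Of these 43 lists, 36 had the 5 tested members required for a test. They were tested with camera in limma at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation and with fry. Camera compares a list with all other tested genes, whereas fry tests whether the members move one way on balance. Some lists share members, so their calls are not independent. FLCN, FNIP1, FNIP2, RRAGC and RRAGD are in both the translocation RCC and the mTORC1 list, and SQSTM1 is in the translocation RCC and autophagy lists.

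Genes are named by a rule. TFE3, PRCC, CDK8, CDK19, CCNC, MED12 and MED13 are always named. Named too are the 6 genes with the highest and the 6 with the lowest log2 change among called genes with a mean FPKM of at least 2 in the higher group, no overlap of libraries between the groups (not asked of the interaction) and a symbol that is not an Ensembl, clone, LINC or LOC name. Of each called list, the 4 members with the smallest adjusted p in the direction of the list may be named, and of an uncalled list at most 2 members. Genes named under the first 3 parts may also be given in other comparisons. Some genes that the rule covers are not reported here. The groups, comparisons, tests, lists, naming rule and the alternatives other than those said to be added later were fixed before the data were examined.

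A Dox score per library was the mean log2(FPKM + 1) of genes that rose at least 2-fold with Dox minus that of genes that fell at least 2-fold, with genes chosen from the Dox change averaged over both inhibitor states (22 rose and 18 fell). It was compared between groups with two-sided exact permutation tests, whose smallest possible p for 3 against 3 libraries is 0.1. Genes called for Dox without inhibitor that were called in the opposite direction for the inhibitor in the presence of Dox were counted as moved back, and the count was set beside 50 simulations in which the Dox plus inhibitor group had the means of the Dox group, and beside the overlap of independent lists.

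Replicate numbers are shared by the groups. Deviations from group means correlated at 0.55, 0.13 and 0.34 between same-numbered libraries of the inhibitor and the Dox plus inhibitor groups. All 3 exceed 0.1, the minimum set for treating numbers as pairs, so the comparison of these groups is also given with a replicate block. The labels do not say what a number stands for, so this pairing is inferred from the values. In no other pair of groups compared did all 3 correlations exceed 0.1, but those of the inhibitor and vehicle groups were 0.69, 0.1 and 0.51. A replicate effect shared by those groups is therefore not excluded by this rule. On the second principal component (19.2% of the variance) replicates 1, 2 and 3 lay in the same order in vehicle (29.7, 10.6 and 1.2), inhibitor (16.4, -3.7 and -12.7) and Dox plus inhibitor libraries (-3.8, -18.5 and -19.3). With Dox alone they lay at 1.7, 1.8 and -3.4. The main fit has no block, so such an effect stays in its estimate of the spread.

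Alternatives were a pseudocount of 0.1, no filter on low values, a mean FPKM of at least 5, median-ratio scaling, quantile normalization, no intensity trend, a fit of only the groups compared, a replicate block, each library left out in turn, and Dox score genes chosen without inhibitor. Added later were leaving out replicate 1 of all groups, and removing a smooth trend on transcript length and GC content, with and without the block. The conditions under which trend removal and the contractile list were treated as deciding nothing were set after their values were seen. Length and GC content were taken from the longest GENCODE v29 transcript of a gene (GRCh38) for 12406 tested genes (98.1%), and gene positions come from the same annotation. The model was tested on simulated data for 12649 genes, 200 of them with a known change. These 200 were drawn only from genes well above the low-value filter in vehicle, and the simulated noise was independent between libraries. The shares that follow therefore do not cover genes near the filter or effects shared by replicate number. The 2-group comparisons called 79.4% to 85.2% of genes changed by 0.5 on the log2 scale, 95.5% to 97% of those changed by 1 and 100% of those changed by 2. For the interaction the corresponding shares were 42.4%, 90.3% and 95.2%. Tables and figures were prepared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.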

Results

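PRCC-TFE3 is a fusion of the PRCC gene with TFE3, a transcription factor of the MiT/TFE family that acts on genes for lysosomes and nutrient sensing. HK-2 cells with an inducible copy of the fusion gene were compared with and without doxycycline (Dox), and with and without the CDK8 and CDK19 inhibitor MSC2530818, after 48 h. The comparisons ask which transcripts change when the fusion gene is induced, and whether inhibition of the Mediator kinases alters that response. Poly(A) RNA was sequenced in 12 libraries, 3 per condition, and 12649 genes were tested. FPKM sums per library ran from 429208 to 473950, and the absolute depth is unknown. FPKM values below are means ± SD over n = 3 libraries. The 10 genes with the highest values took 6.2% to 7.6% of the sum. On the first principal component (49.1% of the variance) the libraries with inhibitor lay from -37.5 to -2.7 and those without it from -2 to 30.9.

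TFE3 (chromosome X, 49028726 to 49043486, minus strand, GRCh38) stood at 35.8 ± 3.1 FPKM in vehicle and 150 ± 4 with Dox, a rise of 2.04 ± 0.07 on the log2 scale (adjusted p = 1.4e-08). With the inhibitor it stood at 27.8 ± 1.7 without Dox and 84.2 ± 3.1 with it, a rise of 1.57 ± 0.07 (adjusted p = 3.4e-07). PRCC (chromosome 1, 156750610 to 156800817, plus strand), the other fusion partner, rose from 28.5 to 41.7 FPKM with Dox (0.54, adjusted p = 0.0035). In the presence of the inhibitor PRCC was called at 0.32 with Dox (adjusted p = 0.049), a call that ended after median-ratio scaling (0.23), after quantile normalization (0.25) and without any one of DMSO 2, Dox 1 to 3, Dox plus inhibitor 1 or 3, or inhibitor 2 or 3 (0.23 to 0.33). Among the other members of the MiT/TFE family, MITF (13.8 to 16.3 FPKM over the groups) was called in none of the comparisons, and TFEB fell with the inhibitor from 1.43 to 0.57 FPKM without Dox and from 1.56 to 0.7 with it. Of the 7 tested members of the Mediator kinase module, which carries the targets of the inhibitor, 0 were called for Dox without inhibitor. CDK8 lay between 10.3 and 12.2 FPKM, CDK19 between 6.96 and 8.8, the cyclin gene CCNC between 44.1 and 60.7, MED12 between 12.8 and 14.9 and MED13 between 11.1 and 17.1 FPKM in the 4 groups. For Dox with the inhibitor 2 of the 7 were higher (3 adjusted over the list alone, and 0 after median-ratio scaling), and fry called the list (adjusted p = 0.014). In single comparisons CDK19 was called for Dox with the inhibitor (0.3, adjusted p = 0.038) and MED12 for the inhibitor without Dox (-0.2, adjusted p = 0.036). The CDK19 call ended under both rescalings (0.22 and 0.19) and without any one of 8 libraries (DMSO 2, Dox 1 to 3, inhibitor 1 or 2, Dox plus inhibitor 2 or 3, values 0.22 to 0.32), and the MED12 call under both rescalings (-0.09 and -0.1) and without any one of 5 (DMSO 1 or 2, inhibitor 1 or 3, Dox plus inhibitor 3, values -0.2 to -0.14).

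**Figure D1:**
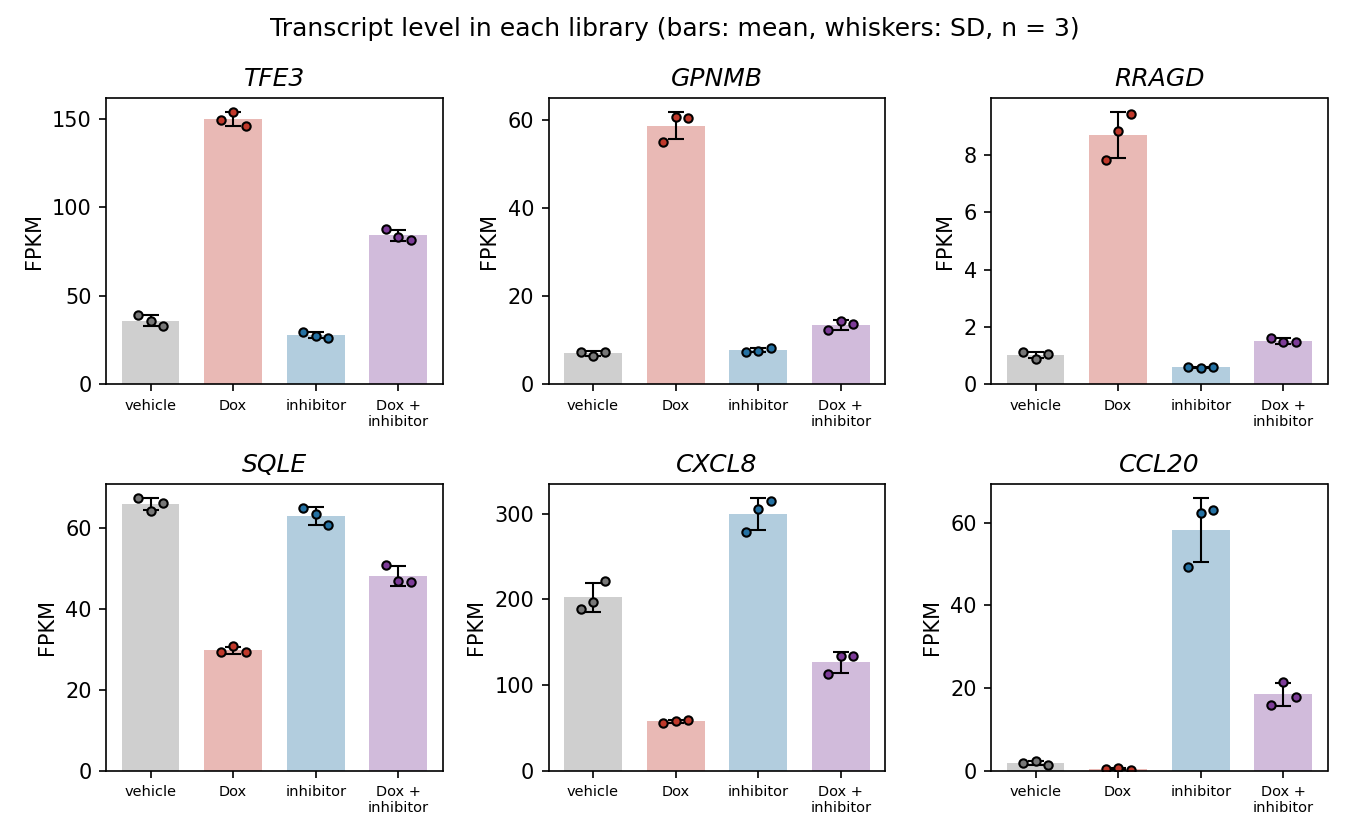
Transcript level in FPKM (vertical axis) of 6 genes in vehicle, Dox, inhibitor and Dox plus inhibitor cells (horizontal axis), with bars for means, whiskers for SD and points for the 3 libraries of each group. TFE3 rises with Dox to 150 FPKM without and to 84.2 FPKM with the inhibitor, GPNMB to 58.6 and 13.4, while CCL20 stands at 58.2 FPKM with the inhibitor alone against 1.9 in vehicle.

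Dox without inhibitor raised markers of translocation renal carcinoma and genes of the lysosomal membrane and proton pump, and lowered genes of cholesterol synthesis. GPNMB, a glycoprotein used as a marker of this carcinoma (chromosome 7, 23235967 to 23275108, plus strand), rose from 7.02 ± 0.51 to 58.6 ± 3.1 FPKM (log2 change 2.9 ± 0.08, adjusted p = 3.6e-09). NMRK2, a nicotinamide riboside kinase (chromosome 19, 3933103 to 3942416, plus strand), rose from 0.12 to 15.2 FPKM (3.85 ± 0.16, adjusted p = 9.8e-08), and RRAGD, a Rag GTPase that signals to mTORC1, rose by 2.26 ± 0.08 (adjusted p = 2.6e-08). The neutrophil chemokine gene CXCL8 fell by 1.8 ± 0.08 (adjusted p = 1.5e-07), from 202 ± 17 to 57.4 ± 1.9 FPKM. SQLE, an oxidizing enzyme of cholesterol synthesis (chromosome 8, 124998497 to 125022283, plus strand), fell by 1.12 ± 0.05 (adjusted p = 1.5e-07), from 65.8 to 29.7 FPKM.

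Other large rises were those of the protease inhibitor SPINK1 (2.86), UAP1L1 (2.5), the renin-binding protein RENBP (2.38) and the hyaluronan-binding protein CEMIP (2.29). Large falls were those of the cytokine genes IL11 (-1.43) and CSF2 (-1.22) and the EGF receptor ligand gene EREG (-1.27). MIR320C1 was listed lower as well (-2.43), but short RNA genes are uncertain in a poly(A) library. Of 14 translocation RCC markers, 11 rose (11 adjusted over the list alone), among them the ubiquitin ligase gene TRIM63 (1.88) and RRAGC (1.38). Of 40 genes for lysosomal membrane and trafficking, 30 rose (32 adjusted over the list alone). Examples were the mannose 6-phosphate receptor gene IGF2R at 0.74, the sialic acid transporter gene SLC17A5 at 1.02 and the cystine transporter gene CTNS at 0.8. Of 19 subunits of the V-ATPase, the proton pump of the lysosome, 14 rose (16 adjusted over the list alone). Among them were ATP6V1A at 0.95 and ATP6V1H at 0.79. Of 47 lysosomal hydrolases 31 rose and 1 fell (32 and 1 adjusted over the list alone). Members were the peptidase gene TPP1 at 1.08 and the phosphatase gene ACP5 at 1.49 (list adjusted p = 0.082 with an estimated correlation). Amino acid sensing to mTORC1 had 11 of 34 members higher (13 adjusted over the list alone), among them the folliculin partner gene FNIP2 (1.5) and the folliculin gene FLCN (1.02), which limit TFE3 activity. Autophagy had 13 of 39 higher (14 adjusted over the list alone), with the receptor genes SQSTM1 at 0.9 and BNIP3 at 0.53. The melanocyte pigment list had 4 of 6 tested members higher (4 adjusted over the list alone), GPNMB and the pigment trafficking gene RAB38 (0.85) among them. Called as higher with the preset correlation but not with an estimated one were fatty acid oxidation (7 of 20 rose and 1 fell, CPT1A at 0.5, adjusted p = 0.082 with an estimated correlation), hypoxia response (7 of 18 rose and 1 fell, EPAS1 at 0.58, adjusted p = 0.059 with an estimated correlation) and glycolysis (6 of 23 rose and 1 fell, ENO2 at 0.92, adjusted p = 0.49 with an estimated correlation). Adjusted over the list alone these counts were 8 and 1, 7 and 1, and 6 and 1.

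Of 24 genes of cholesterol synthesis, 18 fell (19 adjusted over the list alone) and none rose, with CYP51A1 at -0.67, HMGCS1 at -0.93 and MVD at -1.11. Of 25 TGF-beta and SMAD targets, 14 fell and 1 rose (18 and 2 adjusted over the list alone). These included LTBP2 at -0.91 and TGFBI at -0.72. Proximal tubule injury markers fell in 9 of 16 cases and rose in 2 (10 and 2 adjusted over the list alone). Examples were the keratin gene KRT7 at -0.93 and the hyaluronan receptor gene CD44 at -0.54. Angiogenic and growth factors fell in 8 of 21 cases and rose in 3 (10 and 3 adjusted over the list alone). Among them were PDGFB at -1.05 and the EGF receptor ligand gene AREG at -0.98. Wnt/beta-catenin targets fell in 5 of 11 cases and rose in 1 (5 and 1 adjusted over the list alone). Members were TNFRSF19 at -0.86 and MYC at -0.74. Mesenchymal and extracellular matrix genes fell in 7 of 19 cases and rose in 1 (9 and 2 adjusted over the list alone). These included the fibrillin gene FBN1 at -0.42 and the collagenase gene MMP1 at -0.69. NF-kB and inflammatory cytokines fell in 14 of 25 cases and rose in 2 (15 and 4 adjusted over the list alone). Examples were LIF at -0.62 and IL6 at -0.83 (list adjusted p = 0.082 with an estimated correlation). Of 26 immediate early genes, 16 fell and 0 rose (17 and 1 adjusted over the list alone). Among them were CTGF and JUNB at -0.89 each (list adjusted p = 0.082 with an estimated correlation). Cytosolic ribosomal proteins had 10 of 78 members lower (9 adjusted over the list alone), at a median of -0.18 (list adjusted p = 0.39 with an estimated correlation, and 0.18 after quantile normalization). Epithelial junctions and keratins had 8 of 22 lower and 1 higher (8 and 2 adjusted over the list alone). CLDN1 was at -0.52 (list adjusted p = 0.37 with an estimated correlation). G2/M and mitosis was called as lower with 4 of 41 members lower (2 adjusted over the list alone), with a median of -0.06, a mean of 0.02 and adjusted p = 0.28 with an estimated correlation. After median-ratio scaling 20 ribosomal protein genes and 8 of G2/M and mitosis were lower.

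In all, 2269 genes were called in this comparison (17.9%), 1344 higher and 925 lower, with 71 and 21 of them changed at least 2-fold. The called genes were higher in 59.2% of cases in the values as deposited, 43.4% after median-ratio scaling and 43.3% after quantile normalization. Over genes, log2 change and transcript GC content had a rank correlation of -0.39, and 2067 calls remained after the length and GC trend was removed. The count was 1492 without DMSO replicate 2 and 1427 without Dox replicate 3, and the list calls ended without DMSO replicate 3 for G2/M (adjusted p = 0.17) and glycolysis (0.073), and for epithelial junctions without Dox replicate 1 (0.098), without Dox plus inhibitor replicate 2 (0.051) and under either rescaling (0.051 and 0.057). Calls also ended after quantile normalization for G2/M (0.19), with a mean FPKM of at least 5 for G2/M (0.061) and epithelial junctions (0.068), and for the latter with no filter (0.079) or the length and GC trend removed (0.054, and 0.079 with the block).

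In the presence of the inhibitor, Dox again raised GPNMB (0.73 ± 0.08, adjusted p = 1.2e-04), from 7.71 ± 0.49 to 13.4 ± 1 FPKM, and RRAGD (0.66, adjusted p = 3.5e-04). Next to TFE3, the largest rises named here were those of the kinetochore gene CENPT (chromosome 16, 67828157 to 67847811, minus strand), from 23.8 ± 0.48 to 71.4 ± 1.5 FPKM (1.55 ± 0.05, adjusted p = 7.3e-08), and of C21orf91 (chromosome 21, 17788967 to 17819386, minus strand), from 1.01 to 4.81 FPKM (1.53 ± 0.15, adjusted p = 9.6e-05). The same 2 genes rose by 1.91 and 1.93 without inhibitor. The chemokine gene CCL20 fell from 58.2 ± 7.8 to 18.4 ± 2.8 FPKM (-1.61 ± 0.15, adjusted p = 7.7e-05). The interferon-induced GTPase gene GBP2 rose by 1.24. IQCD (-1.62) and the tissue plasminogen activator gene PLAT (-1.66) fell. SNORA45A (1.31) and MIR1307 (-1.6), both short RNA genes whose calls ended without any one of 4 libraries with the inhibitor, and the read-through gene MINOS1-NBL1 (-1.99) are uncertain. SNORA45A stood at 1.02 to 1.29 without Dox plus inhibitor 1 or 2 or inhibitor 1 or 3, and MIR1307 at -1.53 to -1.24 without Dox plus inhibitor 2 or 3 or inhibitor 1 or 2.

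Of 25 NF-kB and inflammatory cytokine genes, 16 fell and 0 rose (19 and 0 adjusted over the list alone). Members were CXCL8 at -1.24 and TNF at -0.94 (list adjusted p = 0.068 with an estimated correlation). Immediate early genes fell in 14 of 26 cases (15 adjusted over the list alone, with 1 higher there), with KLF6 at -0.52 (list adjusted p = 0.14 with an estimated correlation). Lower lists with an adjusted p of 0.086 with an estimated correlation were TGF-beta and SMAD targets (10 of 25 fell and 2 rose, LTBP2 at -0.88), cholesterol synthesis (6 of 24 fell, SQLE at -0.38), proximal tubule injury (4 of 16 fell and 1 rose, PLAU at -0.58), mesenchymal genes (6 of 19 fell and 1 rose, FN1 at -0.86) and growth factors (6 of 21 fell and 3 rose, AREG at -1.23). Adjusted over the list alone these counts were 10 and 2, 8 and 0, 4 and 2, 6 and 1, and 7 and 4. Wnt/beta-catenin targets had 4 of 11 lower and 1 higher (4 and 1 adjusted over the list alone), CCND1 at -0.6 (list adjusted p = 0.068 with an estimated correlation). Of the lists called as higher, translocation RCC markers had 6 of 14 members higher (7, and 1 lower, adjusted over the list alone). RRAGC was at 0.68 (list adjusted p = 0.27 with an estimated correlation). V-ATPase subunits had 7 of 19 higher (9 adjusted over the list alone). ATP6V1A was at 0.82 (list adjusted p = 0.14 with an estimated correlation). Lysosomal membrane and trafficking had 12 of 40 higher (18 adjusted over the list alone). IGF2R was at 0.41 (list adjusted p = 0.28 with an estimated correlation). Lysosomal hydrolases had 16 of 47 higher and 2 lower (19 and 2 adjusted over the list alone). NEU1 was at 0.67 (list adjusted p = 0.48 with an estimated correlation). G2/M and mitosis had 11 of 41 members higher (11 adjusted over the list alone). KIF20A was at 0.33 (list adjusted p = 0.28 with an estimated correlation), and the KIF20A call ended after median-ratio scaling (0.24). Also called as lower were the MHC class I list (3 of 16 lower and 3 higher, 4 and 3 adjusted over the list alone, adjusted p = 0.48 with an estimated correlation), ribosomal proteins (0 of 78 called, 0 adjusted over the list alone, median -0.09, adjusted p = 0.53 with an estimated correlation) and epithelial junctions (7 of 22 lower and 2 higher, 7 and 4 adjusted over the list alone, adjusted p = 0.41 with an estimated correlation). The epithelial list had a median of 0.03 and a mean of -0.1, and its median turned to -0.04 after median-ratio scaling and -0.05 after quantile normalization, which ended its call. After median-ratio scaling the counts were 1 higher for G2/M and mitosis, 4 higher for lysosomal membrane and trafficking, 9 higher and 3 lower for lysosomal hydrolases, 10 lower for cholesterol synthesis, 5 lower and 1 higher for MHC class I and 5 lower for ribosomal proteins.

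In this comparison 2304 genes were called (18.2%), 1537 higher and 767 lower, with 12 and 26 changed at least 2-fold, and 4548 were called with the replicate block. The NRF2 antioxidant list, not called without the block, was called as lower with it (adjusted p = 0.027), and so were CCNC (0.26, adjusted p = 0.027) and MED13 (adjusted p = 0.021) as higher. The called genes were higher in 66.7% of cases as deposited, 35.3% after median-ratio scaling and 41% after quantile normalization. Over genes, log2 change and transcript GC content had a rank correlation of -0.56, and 1834 calls remained after the length and GC trend was removed. The count was 1245 without Dox plus inhibitor replicate 2, 1121 without Dox plus inhibitor replicate 3 and 1352 without inhibitor replicate 2, and the calls ended for MHC class I without Dox plus inhibitor replicate 3 (adjusted p = 0.071) or inhibitor replicate 1 (0.12) and for lysosomal hydrolases without inhibitor replicate 3 (0.073). Quantile normalization ended the calls of MHC class I (0.2), ribosomal proteins (0.25) and proximal tubule injury (0.084). The MHC class I call also ended with the length and GC trend removed (0.15, and 0.1 with the block) and without replicate 1 of all groups (0.055), and that of epithelial junctions with no filter (0.071) and with the trend removed and the block (0.069).

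With the inhibitor and without Dox, the 2 largest rises named here were those of genes for secreted factors. CCL20, a chemokine for lymphocytes and dendritic cells (chromosome 2, 227805739 to 227817564, plus strand), rose from 1.9 ± 0.47 to 58.2 ± 7.8 FPKM (log2 change 4.36 ± 0.15, adjusted p = 1.4e-08). PDGFB, which codes for a chain of platelet-derived growth factor (chromosome 22, 39223359 to 39244751, minus strand), rose from 6.06 ± 0.64 to 59.4 ± 4.1 FPKM (3.1 ± 0.08, adjusted p = 2.7e-09). TNF rose by 2.39 ± 0.1 (adjusted p = 4.1e-08). PDZK1, a scaffold for transporters of the proximal tubule brush border (chromosome 1, 145670852 to 145708148, minus strand), fell from 43 ± 0.27 to 9.74 ± 0.54 FPKM (-2.04 ± 0.05, adjusted p = 2.2e-09).

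Large rises were also those of IQCD (2.52), CITED4 (2.49) and the atrial myosin light chain gene MYL7 (2.47), and large falls those of MIR503HG (-2.15), the immediate early gene EGR1 (-1.89) and the autotaxin gene ENPP2 (-1.74). Over all genes the median change was -0.117, and -0.012 after median-ratio scaling, so list medians are also given relative to the median of all genes. Of 41 genes of G2/M and mitosis, 32 fell and 0 rose (33 and 0 adjusted over the list alone), at a median of -0.68, or -0.56 relative to all genes (list adjusted p = 0.091 with an estimated correlation). The kinesin gene KIF20A was at -1.45 and the kinase gene AURKA at -0.89. Of 40 genes of G1/S and DNA replication, 31 fell and 1 rose (33 and 1 adjusted over the list alone), at a median of -0.42, or -0.3 relative to all genes (list adjusted p = 0.16 with an estimated correlation). The ribonucleotide reductase genes RRM2 and RRM1 were at -1.31 and -0.89. NF-kB and inflammatory cytokines rose in 17 of 25 cases and fell in 2 (18 and 2 adjusted over the list alone), at a median of 0.52, or 0.64 relative to all genes, with CSF1 at 1.06 and NFKBIA at 1.16 (list adjusted p = 0.13 with an estimated correlation). TGF-beta and SMAD targets rose in 16 of 25 cases and fell in 4 (17 and 5 adjusted over the list alone), at a median of 0.51, or 0.63 relative to all genes, with the smooth muscle actin gene ACTA2 at 2.08 and the transgelin gene TAGLN at 1.73 (list adjusted p = 0.13 with an estimated correlation). Antigen presentation by MHC class I had 9 of 16 members higher (9 adjusted over the list alone), at a median of 0.34, or 0.45 relative to all genes, with the peptide transporter gene TAP1 at 0.87 (list adjusted p = 0.23 with an estimated correlation). Proximal tubule injury markers rose in 9 of 16 cases and fell in 3 (9 and 3 adjusted over the list alone), at a median of 0.27, or 0.38 relative to all genes, with the osteopontin gene SPP1 at 1.46 and the urokinase gene PLAU at 1.08 (list adjusted p = 0.091 with an estimated correlation). Mesenchymal and extracellular matrix genes rose in 8 of 19 cases and fell in 3 (8 and 3 adjusted over the list alone), at a median of 0.08, or 0.2 relative to all genes, with fibronectin (FN1) at 1.22 and tenascin-C (TNC) at 1.43 (list adjusted p = 0.13 with an estimated correlation). Immediate early genes rose in 12 of 26 cases and fell in 4 (12 and 6 adjusted over the list alone), at a median of 0.15, or 0.27 relative to all genes, with SRF at 0.84 and EGR1 among those that fell (list adjusted p = 0.59 with an estimated correlation). Proximal tubule genes rose in 4 of 12 cases and fell in 2 (6 and 2 adjusted over the list alone), at a median of 0.2, or 0.31 relative to all genes, with GATM at 0.91 and PAX8 at 0.51 (list adjusted p = 0.16 with an estimated correlation). Fatty acid and triglyceride synthesis had 5 of 20 higher (5 adjusted over the list alone), at a median of 0.07, or 0.19 relative to all genes, with the desaturase gene SCD at 0.91 (list adjusted p = 0.24 with an estimated correlation). Nuclear OXPHOS subunits had 29 of 76 lower and 1 higher (29 and 1 adjusted over the list alone), at a median of -0.18, or -0.06 relative to all genes, with NDUFS7 at -0.66 (list adjusted p = 0.76 with an estimated correlation). After median-ratio scaling 9 OXPHOS subunits were lower and 2 higher, and 8 genes of fatty acid and triglyceride synthesis were higher.

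This comparison had 4802 called genes (38%), 1479 higher and 3323 lower, with 161 and 72 changed at least 2-fold. With the replicate block 6167 were called. The called genes were higher in 30.8% of cases as deposited, 55% after median-ratio scaling and 49.7% after quantile normalization. Median-ratio scaling ended the calls of OXPHOS subunits (adjusted p = 0.12), immediate early genes (0.065) and proximal tubule genes (0.079), and so did leaving out DMSO replicate 1 (0.19), inhibitor replicate 2 (0.11) or inhibitor replicate 3 (0.15) for OXPHOS, and inhibitor replicate 1 for immediate early (0.074) and proximal tubule genes (0.054). Removal of the length and GC trend ended those of OXPHOS (0.063) and proximal tubule genes (0.064). The proximal tubule call also ended after quantile normalization (0.055) and with a mean FPKM of at least 5 (0.27), and that of immediate early genes with no filter (0.068).

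In the presence of Dox, the inhibitor lowered many of the genes that Dox raised. NMRK2 fell from 15.2 to 0.607 FPKM (-3.36 ± 0.16, adjusted p = 1.0e-07), GPNMB from 58.6 ± 3.1 to 13.4 ± 1 FPKM (-2.05 ± 0.08, adjusted p = 2.0e-08) and RRAGD by 1.95 ± 0.08 (adjusted p = 3.5e-08). CCL20 rose by 3.81 ± 0.15 (adjusted p = 3.1e-08) and PDGFB by 3.15 ± 0.08 (adjusted p = 4.0e-09). The endothelin gene EDN1 rose from 2.38 to 22.9 FPKM (2.82 ± 0.08, adjusted p = 4.0e-09) and ACTA2 (chromosome 10, 88935074 to 88991339, minus strand) from 0.277 to 7.84 FPKM (2.8 ± 0.1, adjusted p = 1.9e-08). TFE3 itself fell by 0.82 (adjusted p = 5.0e-06) and PRCC by 0.53 (adjusted p = 0.0021), against -0.35 (adjusted p = 0.0018) and -0.31 (adjusted p = 0.029) for the inhibitor without Dox, where the PRCC call ended under both rescalings (-0.2 and -0.22) and without any one of DMSO 1, DMSO 2, inhibitor 2 or inhibitor 3 (-0.33 to -0.24).

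Also large were the rise of C8orf4 (2.38) and the falls of SPINK1 (-2.2) and the prostaglandin D synthase gene PTGDS (-2.1). The short RNA genes MIR6516 (3.56, no longer called without Dox 1, 2 or 3 or Dox plus inhibitor 2, at 3.31 to 3.56), MIR1307 (-2.53) and SNORD116-22 were called too and are uncertain. Of 14 translocation RCC markers, 10 fell (10 adjusted over the list alone). TRIM63 was at -1.86 (list adjusted p = 0.1 with an estimated correlation). V-ATPase subunits fell in 16 of 19 cases and rose in 1 (17 and 1 adjusted over the list alone). ATP6V1A was at -1.29 (list adjusted p = 0.06 with an estimated correlation). Lysosomal membrane and trafficking had 25 of 40 lower (27 adjusted over the list alone), with the lysosomal channel gene MCOLN1 at -1.08 and the cholesterol exporter gene NPC1 at -0.54, and autophagy had 17 of 39 lower and 1 higher (17 and 2 adjusted over the list alone), with NBR1 at -0.58 (both adjusted p = 0.12 with an estimated correlation). Lysosomal hydrolases fell in 21 of 47 cases and rose in 1 (21 and 3 adjusted over the list alone). Examples were the sialidase gene NEU1 at -1.59 and the sphingomyelinase gene SMPD1 at -1.33 (list adjusted p = 0.39 with an estimated correlation). Amino acid sensing to mTORC1 had 14 of 34 lower and 2 higher (15 and 2 adjusted over the list alone). FLCN was at -0.75 (list adjusted p = 0.14 with an estimated correlation). G1/S genes fell in 29 of 40 cases (30 adjusted over the list alone), with RRM2 at -1.01 (list adjusted p = 0.13 with an estimated correlation), and G2/M genes in 25 of 41 (26 adjusted over the list alone), with KIF20A at -0.9 (list adjusted p = 0.12 with an estimated correlation). Also called as lower were fatty acid oxidation (8 of 20 lower and 2 higher, 12 and 2 adjusted over the list alone, ETFA at -0.33) and melanocyte pigment genes (3 of 6 lower, 3 adjusted over the list alone), both with adjusted p = 0.18 with an estimated correlation. The TCA cycle (8 of 25 lower, 8 adjusted over the list alone, PC at -0.85) and OXPHOS subunits (23 of 76 lower, 23 adjusted over the list alone) had adjusted p = 0.26 and 0.67 with an estimated correlation. Autophagy, fatty acid oxidation and the TCA cycle had medians of -0.2, -0.23 and -0.13 here (-0.12, -0.15 and -0.05 relative to all genes). For the inhibitor without Dox, where camera did not call them, the medians were -0.19, -0.31 and -0.18 (-0.07, -0.19 and -0.06 relative to all genes). Their falls are therefore not particular to cells with Dox.

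Proximal tubule injury markers rose in 11 of 16 cases and fell in 2 (11 and 2 adjusted over the list alone), with KRT7 at 1.01 and PLAU at 0.88, and were the only list of this comparison called with an estimated correlation too (list adjusted p = 0.034 with an estimated correlation). TGF-beta and SMAD targets rose in 15 of 25 cases and fell in 5 (15 and 5 adjusted over the list alone). Among them were TAGLN at 2.24 and CTGF at 1.46 (list adjusted p = 0.1 with an estimated correlation). NF-kB and inflammatory cytokines rose in 14 of 25 cases and fell in 2 (14 and 2 adjusted over the list alone). Members were TNF at 2.11 and CXCL8 at 1.12 (list adjusted p = 0.14 with an estimated correlation). Mesenchymal genes rose in 6 of 19 cases and fell in 3 (7 and 4 adjusted over the list alone). TNC was at 1.64 (list adjusted p = 0.12 with an estimated correlation). Immediate early genes rose in 10 of 26 cases and fell in 7 (11 and 7 adjusted over the list alone). SRF was at 1.15 (list adjusted p = 0.52 with an estimated correlation). MHC class I genes had 7 of 16 higher and 2 lower (7 and 3 adjusted over the list alone). TAP1 was at 0.93 (list adjusted p = 0.43 with an estimated correlation). Cholesterol synthesis (7 of 24 rose and 3 fell, 8 and 3 adjusted over the list alone, SQLE at 0.67) and fatty acid synthesis (7 of 20 rose and 1 fell, 7 and 3 adjusted over the list alone, SCD at 0.81) both had adjusted p = 0.18 with an estimated correlation. Replication-dependent histones had 4 of 6 members higher and 1 lower (4 and 1 adjusted over the list alone), with HIST1H2BK at 1.39 (list adjusted p = 0.13 with an estimated correlation), and Wnt/beta-catenin targets had 6 of 11 higher and 2 lower (6 and 3 adjusted over the list alone), with MYC at 0.75 (list adjusted p = 0.15 with an estimated correlation). Values of histone, HLA and ribosomal protein genes are uncertain, since reads can be shared with close copies.

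In this comparison 4063 genes were called (32.1%), 1434 higher and 2629 lower, with 123 and 79 changed at least 2-fold. The called genes were higher in 35.3% of cases as deposited, 53.9% after median-ratio scaling and 50.3% after quantile normalization. Median-ratio scaling ended the calls of OXPHOS subunits (adjusted p = 0.07), the TCA cycle (0.074), fatty acid oxidation (0.05) and Wnt targets (0.057), and left 14 OXPHOS subunits lower and 3 higher. Leaving out 1 library ended those of OXPHOS (0.064 to 0.079 without Dox 1, Dox plus inhibitor 2 or Dox plus inhibitor 3), fatty acid oxidation (0.052 to 0.069 without Dox 2, Dox plus inhibitor 2 or Dox plus inhibitor 3) and MHC class I (0.058 without Dox 1). With no filter the calls of melanocyte pigment genes (0.13), histones (0.075), Wnt targets (0.064) and immediate early genes (0.05) ended. Removal of the length and GC trend ended those of OXPHOS (0.067) and Wnt targets (0.072), a mean FPKM of at least 5 that of the TCA cycle (0.065), a pseudocount of 0.1 that of fatty acid oxidation (0.052), and leaving out replicate 1 of all groups those of MHC class I (0.066) and Wnt targets (0.064).

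**Figure D2:**
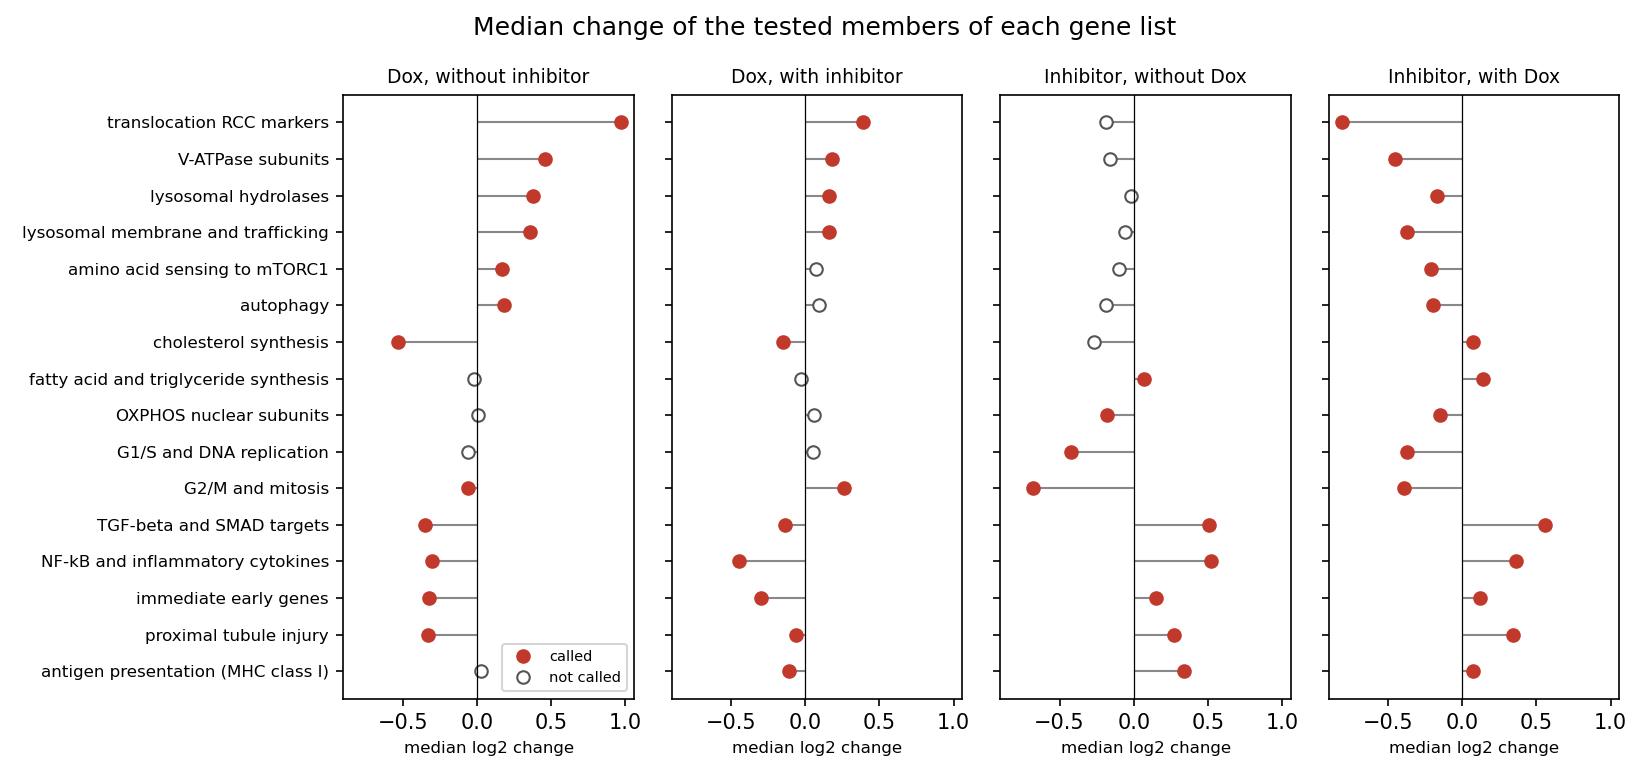
Median log2 change (horizontal axis) of the tested members of 16 gene lists (vertical axis) in the 4 comparisons, with filled points for lists called by camera at its preset correlation and open points for lists not called. Translocation RCC markers have medians of 0.97 for Dox without inhibitor, 0.39 for Dox with it and -0.81 for the inhibitor with Dox, while G2/M and mitosis lies at -0.68 for the inhibitor without Dox.

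Many rises with Dox were smaller in the presence of the inhibitor. The interaction, the Dox change with the inhibitor minus the Dox change without it, was -3.3 ± 0.23 for NMRK2 (adjusted p = 3.4e-05), -2.17 ± 0.11 for GPNMB (adjusted p = 4.3e-06) and -1.8 ± 0.11 for TRIM63 (adjusted p = 2.0e-05), which stood at 2.85 FPKM with Dox and 0.0567 FPKM with Dox plus inhibitor. For UAP1L1 the interaction was -1.72, for RRAGD -1.6, for GAPLINC -2.2 and for SPINK1 -2.29, though the SPINK1 call ended with a pseudocount of 0.1 (adjusted p = 0.05). Positive interactions were those of the endothelin gene EDN2 (1.16 ± 0.18, adjusted p = 0.0059), which stood at 19.6, 14.9, 15.9 and 28 FPKM in vehicle, Dox, inhibitor and Dox plus inhibitor cells, of SDPR (1.1), of the transcription regulator gene ARID5B (1.07) and of the cadherin gene CDH6 (0.95). For TFE3 the interaction was -0.47 ± 0.1 (adjusted p = 0.023), a call that ended without any one of DMSO 2, Dox 1 to 3, Dox plus inhibitor 2 or 3, or inhibitor 2 (-0.49 to -0.45). For PRCC it was -0.22 (adjusted p = 0.57). MIR320C1 (3.24) and SNORA45A (2.24) were called but are uncertain, and each call ended without any one of 9 libraries (3.14 to 3.34 for MIR320C1 without a DMSO, Dox or inhibitor library, and 1.95 to 2.39 for SNORA45A without a Dox library, DMSO 2 or 3, inhibitor 1 or 3, or Dox plus inhibitor 1 or 2).

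Of 14 translocation RCC markers, 8 had a negative interaction (8 adjusted over the list alone), at a median of -0.65. Lysosomal membrane and trafficking had 7 of 40 (15, and 1 positive, adjusted over the list alone), with SLC17A5 and MCOLN1 at -0.83 each. V-ATPase subunits had 4 of 19 (10 adjusted over the list alone), with ATP6V0E1 at -0.45. Amino acid sensing to mTORC1 had 6 of 34 (7 adjusted over the list alone). These included FNIP2 at -1.42, RRAGC at -0.7 and FLCN at -0.59, which are translocation RCC list members too. Melanocyte pigment genes had 2 of 6 (3 adjusted over the list alone), with GPR143, a receptor of pigment organelles, at -0.72. Lysosomal hydrolases had 14 of 47 (19, and 1 positive, adjusted over the list alone). Examples were the cathepsin genes CTSA at -0.93 and CTSD at -0.95 (list adjusted p = 0.15 with an estimated correlation). Cholesterol synthesis had a positive interaction in 4 of 24 members (11 adjusted over the list alone), at a median of 0.35, with SQLE at 0.74 and HMGCS1 at 0.82. G2/M and mitosis had a positive interaction in 2 of 41 (9 adjusted over the list alone). Among them was KIF20A at 0.55 (0.51 and no longer called without Dox replicate 3), at a list median of 0.29. MHC class I had a negative interaction in 1 of 16 members (3 adjusted over the list alone), at a median of -0.15 (list adjusted p = 0.33 with an estimated correlation). Ribosomal proteins had 0 of 78 members called (0 adjusted over the list alone), at a median of 0.1 (list adjusted p = 0.9 with an estimated correlation). NF-kB and inflammatory cytokines had 3 negative and 2 positive of 25 (5 and 2 adjusted over the list alone). An example was the superoxide dismutase gene SOD2 at -0.95 (list adjusted p = 0.65 with an estimated correlation, and 0.051 with the replicate block).

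The interaction was called for 357 genes (2.8%), 115 positive and 242 negative. The count lay between 186 and 237 without any one of DMSO 2 (198), Dox 2 (186), Dox 3 (207), inhibitor 2 (204), Dox plus inhibitor 2 (237) or Dox plus inhibitor 3 (214). The NF-kB call ended without DMSO 3, Dox 2, inhibitor 1 or Dox plus inhibitor 1 or 3 (adjusted p 0.1 to 0.14), and that of ribosomal proteins without DMSO 1, Dox 2 or 3, inhibitor 2 or 3, or Dox plus inhibitor 1 (0.078 to 0.67). Quantile normalization ended both (0.09 and 0.79). The NF-kB call also ended with a pseudocount of 0.1 (0.13), with no filter (0.062) and with the length and GC trend removed (0.12, and 0.079 with the block).

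Of the 2269 genes called for Dox without inhibitor, 1367 (60.2%) were called in the opposite direction for the inhibitor in the presence of Dox, 868 of them higher and 499 lower with Dox, and 124 were called in the same direction. In 50 simulations with no inhibitor effect the count was 0.1 on average and at most 1, and independent lists would share 384. With no inhibitor effect almost no gene can be called for the inhibitor with Dox, so a count near 0 was set in advance. The simulations say nothing about an inhibitor effect unrelated to Dox. Both comparisons use the 3 Dox libraries, which are too few to divide, so part of the excess may come from them. Of the 71 genes raised at least 2-fold by Dox, 66 were moved back, 70 had a smaller Dox change with the inhibitor, and 49 had a negative interaction. Of the 21 genes lowered at least 2-fold, 16 were moved back, 17 had a smaller change and 9 had a positive interaction. Of all 2269 genes called for Dox without inhibitor, 1037 were also called in the same direction with it, and 251 had an interaction called against the Dox change. The count of genes moved back can also hold genes that the inhibitor changed likewise without Dox. It is therefore not the share of the Dox response that was undone. The Dox score was -1.13 ± 0.17 in vehicle, 1.68 ± 0.13 with Dox, -2.9 ± 0.1 with the inhibitor and -0.59 ± 0.09 with both (n = 3 each). The difference was -2.27 between Dox plus inhibitor and Dox cells and -1.77 between inhibitor and vehicle cells (-1.17 without DMSO replicate 3, and -0.93 with score genes chosen from the Dox change without inhibitor), with p = 0.1 for each in a two-sided exact permutation test, the smallest value that 3 against 3 libraries allow. With the inhibitor alone the mean log2(FPKM + 1) of the 22 score genes that rise with Dox was 1.93, against 2.16 in vehicle, and that of the 18 that fall was 4.82 against 3.28. The Dox change of the score was 2.8 without and 2.31 with the inhibitor. Its genes were picked by the Dox change averaged over both inhibitor states. That choice leaves out some genes whose rise was lost with the inhibitor, such as TRIM63 and FTH1. The score therefore does not measure how much of the Dox response was kept. The mean of the 22 genes changed by 1.88 without and 0.9 with the inhibitor. That of the 18 genes changed by -0.92 and -1.4, a larger fall with the inhibitor on the log2(FPKM + 1) scale. This scale understates falls of genes low in vehicle. CCL20, 1 of the 18, stood at 1.45 to 2.39 FPKM in vehicle and 49.18 to 62.95 FPKM with the inhibitor alone. The 18 also hold the uncertain MINOS1-NBL1 (-0.07 without and -1.99 with the inhibitor) and the short RNA gene SNORA5B (-0.87 and -1.26).

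**Figure D3:**
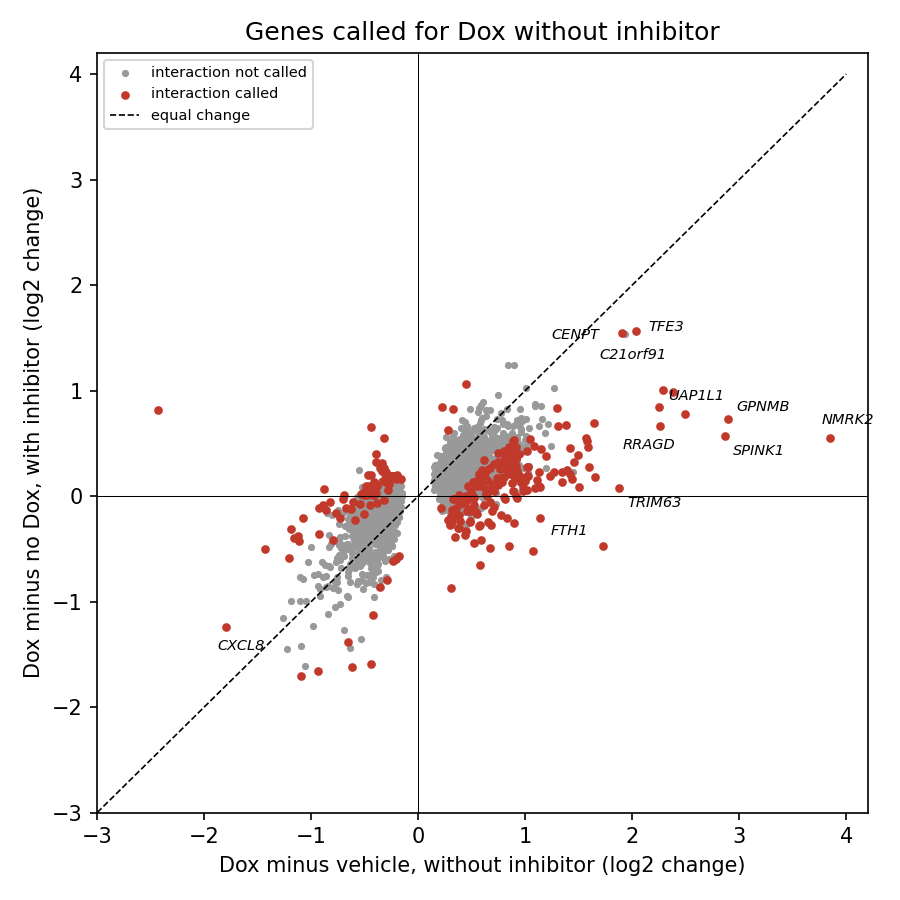
Log2 change with Dox in the presence of the inhibitor (vertical axis) against that without it (horizontal axis), with 1 point for each of the 2269 genes called for Dox without inhibitor, red where the interaction was called, and a dashed line of equal change. GPNMB lies at 2.9 without and 0.73 with the inhibitor, while CENPT lies near the line at 1.91 and 1.55.

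Lists that camera called in none of the 5 comparisons of the fit without a replicate block, at the preset or an estimated correlation, held single members that changed. All of them but the ATF4 list were called by fry in at least 1 comparison, among them the interferon list for Dox without inhibitor (adjusted p = 0.0032) and heat shock proteins for the inhibitor without Dox (3.6e-06). The lists were the ATF4 amino acid response (4 of 31 higher and 5 lower with Dox without inhibitor), CDK inhibitors and p53 targets (5 of 27 and 1), heat shock proteins (1 of 18 and 1), interferon response (6 of 35 and 1), mitochondrial ribosome (2 of 75 and 2), NRF2 antioxidant genes (7 of 24 and 4), unfolded protein response (3 of 22 and 2) and the Mediator kinase module (0 of 7). Adjusted over the list alone these counts were 7 and 8, 5 and 2, 1 and 1, 6 and 1, 1 and 0, 8 and 7, 5 and 5, and 0. After median-ratio scaling they were 4 and 8, 5 and 3, 1 and 5, 5 and 2, 1 and 8, 7 and 7, 0 and 6, and 0. For the inhibitor without Dox the same lists had 6 higher and 11 lower, 5 and 11, 1 and 9, 11 and 9, 1 and 24, 3 and 4, 5 and 3, and 0 and 1 members called, and after median-ratio scaling 8 and 9, 6 and 8, 2 and 5, 11 and 7, 1 and 11, 6 and 2, 9 and 2, and 0 and 0. With the replicate block camera called the NRF2 list for Dox with the inhibitor and the mitochondrial ribosome list for Dox without it. For the inhibitor without Dox the block added the interferon and mitochondrial ribosome lists. Markers of other cell types were mostly below 1 FPKM, in 21 of 24 genes of distal tubule and collecting duct, 7 of 10 of podocytes, 14 of 16 of endothelium, 18 of 19 of leukocytes and 11 of 16 of melanocytes. Of the tested ones, the lysosomal leukocyte marker gene CD68 moved with the lysosomal lists, from 38.6 to 56 FPKM with Dox (0.53, adjusted p = 0.0023) and to 31 FPKM with both, and the tubular claudin gene CLDN16 rose with the inhibitor from 4.63 to 15.8 FPKM (1.57, adjusted p = 2.2e-07). These 2 genes, MITF and TFEB belong to lists with too few tested members and were chosen after their values were seen. Genes of the mitochondrial genome are not in the table.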

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

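The tests on smaller Dox changes were chosen after the result was seen. The genes and lists named first stand out because the Dox change differed with the inhibitor by a test of the difference itself, the interaction, which was called for 357 genes. Of 100 splits of the libraries (the real one included) 4 gave as many called genes or more, and the highest of the others called 1297. That split left the vehicle and inhibitor libraries in their groups and mixed Dox with Dox plus inhibitor libraries, so the inhibitor's own effect without Dox enters its count. The 2 others (422 and 449) likewise kept or exchanged 2 whole groups, so the share of splits is not taken to exclude chance. For the number of called lists, 31 of 100 splits gave at least as many as the real 11 and the highest other gave 20, so chance is not excluded for it.

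Negative list medians were those of translocation RCC markers (-0.65), melanocyte pigment genes (-0.33), lysosomal membrane and trafficking (-0.28), V-ATPase subunits (-0.26), lysosomal hydrolases (-0.18), MHC class I (-0.15), amino acid sensing to mTORC1 (-0.1) and NF-kB (-0.03), and positive ones those of cholesterol synthesis (0.35), G2/M and mitosis (0.29) and ribosomal proteins (0.1). With an estimated correlation the hydrolase, MHC class I, NF-kB and ribosomal protein lists were not called, as given above. Genes of the translocation and mTORC1 lists were NMRK2 (-3.3), GPNMB (-2.17), TRIM63 (-1.8), RRAGD (-1.6), FNIP2 (-1.42), RRAGC (-0.7) and FLCN (-0.59). Lysosomal and pigment genes were the phosphatase gene ACP5 (-1.1), the cathepsin genes CTSD (-0.95) and CTSA (-0.93), SLC17A5 (-0.83), MCOLN1 (-0.83), GPR143 (-0.72), GM2A (-0.69), CTNS (-0.62), M6PR (-0.5), ATP6V1F (-0.53), ATP6V1B2 (-0.45), ATP6V0E1 (-0.45) and ATP6V0A1 (-0.38). Others with a negative interaction were SPINK1 (-2.29), GAPLINC (-2.2), UAP1L1 (-1.72), SOD2 (-0.95), NLRC5 (-0.51), CSF1 (-0.51), TNFAIP3 (-0.48) and TFE3 (-0.47). Positive interactions were those of HMGCS1 (0.82), SQLE (0.74) and CYP51A1 (0.56) of cholesterol synthesis, KIF20A (0.55) and the cyclin gene CCNB1 (0.39) of mitosis, EDN2 (1.16), SDPR (1.1), ARID5B (1.07), CDH6 (0.95), and the short RNA genes MIR320C1 (3.24) and SNORA45A (2.24). Chosen after their values were seen were FTH1 (-1.35), HMOX1 (-1.23), SQSTM1 (-1.15), ANKRD1 (-1.03) and CTGF (0.8). Of these 44 genes, 34 were called without each of the 12 libraries, and 10 were lost without at least 1. The 10 were ATP6V0A1 (-0.41 to -0.34 in the leave-outs that ended the call, all but DMSO 1), ATP6V1B2 (-0.45 to -0.43 without DMSO 2, Dox 2 or inhibitor 2), ATP6V1F (-0.57 to -0.45, all but DMSO 1, inhibitor 3 and Dox plus inhibitor 1), CSF1 (-0.54 to -0.44, all but DMSO 1 and inhibitor 3), NLRC5 (-0.52 to -0.46, all but DMSO 1, Dox 1, inhibitor 1 and inhibitor 3), TFE3 (-0.49 to -0.45), CCNB1 (0.35 to 0.41, all but DMSO 1, DMSO 3, Dox 1 and inhibitor 1), KIF20A (0.51 without Dox 3), MIR320C1 (3.14 to 3.34) and SNORA45A (1.95 to 2.39), with the libraries of TFE3, MIR320C1 and SNORA45A as given above.

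Smaller Dox changes with the inhibitor may reflect a lower level of the TFE3 transcript, which kept 49.5% of its Dox increment in FPKM. Of the 70 genes other than TFE3 raised at least 2-fold by Dox, 63 kept less than that, and their median of 18.6% (quartiles 9.7% to 33.1%) lay -30.9 points from TFE3 (-31.4 to -27.6 with 1 library left out), which argues against a response in proportion to the transcript, while a steeper response and a change at the protein level stay open. Picking genes by their Dox change without inhibitor would also shrink the other change, and of 12 genes picked with the inhibitor instead only 5 rose more without it and 7 rose less. A test with held-out libraries, added because of that outcome, gave the picked genes a median rise of at least 1.03 without inhibitor in libraries not used to pick them, against 0.37 to 0.51 with it, which argues against picking as the whole cause. The pseudocount is argued against by a median interaction of -0.67 (-1.35 to -0.22) in the 22 such genes with at least 10 FPKM in vehicle, and an effect of the inhibitor on transcription by the fusion protein stays open as a biological hypothesis.

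Called genes were lower in 69.2% of cases for the inhibitor without Dox and in 64.7% with it. After median-ratio scaling these shares were 45% and 46.1%, as the scaling of the FPKM values as a source would give, although this scaling would also remove a common shift from other sources. Removal of the trend on transcript length and GC content gave 72.4% and 67.9%, but it keeps the mean of each library and thus the mean change of all genes (medians after it -0.117 and -0.081). Transcript length and GC content therefore cannot be told apart from other sources, and neither can less RNA per cell, since the table lists 0 spike-in transcripts. No biological explanation beyond this was tested.

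The Dox rises of CENPT (1.91 without and 1.55 with the inhibitor) and C21orf91 (1.93 and 1.53) were mostly kept on the log2 scale, unlike those of most genes raised at least 2-fold. In FPKM they kept 75.1% and 55.4% of the Dox increment, against 49.5% for TFE3. Of the 70 other genes raised at least 2-fold, 7 kept more than TFE3, these 2 among them, and some of the 7 kept more than C21orf91. Transcription of the surrounding locus is argued against for CENPT by its 9 tested neighbours within 100 kb, with a median change of -0.11 (-0.32 to 0.03). For C21orf91 this cannot be told apart, as it has 0 tested neighbours in that distance. An effect of Dox without the fusion cannot be told apart from one of the fusion, since 0 groups gave Dox to cells without it. A direct effect of the fusion that does not need the Mediator kinases stays open as a biological explanation.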

How the results depend on the processing

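Removal of a length and GC trend, alone or with the block, and leaving out replicate 1 of all groups were chosen after seeing the data. Of the called results for named genes, 1 reversed, the Dox change of FTL without inhibitor (-0.16 after quantile normalization, which sets the values of the highest genes by rank). The uncalled FTL interaction turned to 0.54 under it too. The majority direction of called genes turned under median-ratio scaling in all 4 comparisons of 2 groups, and so did the median of epithelial junctions for Dox with the inhibitor (0.03 to -0.04). Medians near 0 of the called growth factor and epithelial lists for Dox and of immediate early genes for the inhibitor without Dox turned under at least 1 other alternative. The cause of the shifts below was not tested unless named. With an estimated correlation, called lists numbered 12 (of 21) for Dox without inhibitor, 0 (of 16) for Dox with it, 0 (of 11) for the inhibitor without Dox, 1 (of 22) with Dox and 7 (of 11) for the interaction, and fry called 25 for the inhibitor without Dox. With the replicate block, called genes numbered 3741 (from 2269), 4548 (from 2304) and 666 (from 357) for Dox without inhibitor, Dox with it and the interaction. After the length and GC trend was removed they numbered 3459, 3534 and 1022, with 2165 moved back, and with the block as well 4090, 4406, 1249 and 2511, and 6166 for the inhibitor with Dox. Dox with the inhibitor gave 1099 genes when only its groups were fitted, with fewer samples for the variance. With 1 library left out, the lowest and highest counts in the order of the comparisons were 1427 and 2665, 1121 and 2920, 3683 and 5011, 3057 and 4478, and 186 and 420 genes, 19 and 22, 16 and 21, 11 and 14, 21 and 24, and 9 and 13 lists, and 917 and 1551 genes moved back. The Dox score differences ran from -2.64 to -1.52 (both treatments against Dox) and -1.75 to -1.17 (inhibitor against vehicle), and the latter was -0.93 with score genes chosen from the Dox change without inhibitor. Counts moved by over 1.5 times without DMSO 2 (1492) or Dox 3 (1427) for Dox without inhibitor, without inhibitor 2 (1352), Dox plus inhibitor 2 (1245) or Dox plus inhibitor 3 (1121) for Dox with it, and for the interaction without DMSO 2 (198), Dox 2 (186), Dox 3 (207), inhibitor 2 (204), Dox plus inhibitor 2 (237) or Dox plus inhibitor 3 (214). The inhibitor and Dox plus inhibitor libraries alone met the minimum for pairs, and 8 of the 12 libraries correlated best with another of their own number. Besides the changes given above, the block called CCNC (adjusted p = 0.013), MITF (0.024) and the mitochondrial ribosome list (0.019) for Dox without inhibitor, and the interferon, mitochondrial ribosome and Wnt lists (0.033 each) for the inhibitor without Dox, and the interaction of FTL (0.011), and it changed no other call of a named gene or list. Of 404 results for genes under the naming rule or given in the text, 371 were called, 329 of them under all alternatives, 41 not under at least 1 and 1 reversed, while 12 of 33 uncalled results were called under at least 1. Of 180 list results, 81 were called, 20 of them under all alternatives and list tests, and 48 of 99 uncalled ones were called under at least 1. In the other splits of 3 against 3 libraries (10 with the real one, too few for a share under 0.05) the highest counts of genes were 4, 2, 1 and 1 and of lists 17, 10, 10 and 14 for the 4 comparisons, against 2269, 2304, 4802 and 4063 genes and 21, 16, 11 and 22 lists, and 0 moved back against 1367. These splits mix libraries of the 2 groups, so the treatment effect enters the variance and few genes can be called. The low counts of genes therefore do not measure chance. The other splits still called a median of 11, 8, 7 and 10 lists in the 4 comparisons. Camera at its preset correlation thus called many lists in mixed groups, and such a call alone does not exclude chance. Of the other splits for Dox with the inhibitor, 3 part all 3 pairs as the real one does (highest 0) and 6 part 1 pair (highest 2). In the order of the comparisons, rank correlation of log2 change and GC content was -0.39, -0.56, 0.22, 0.09 and -0.21, and 2067, 1834, 4466, 3837 and 332 of the calls remained after trend removal. The Dox changes thus followed GC content more closely than the inhibitor changes did. With transcript length they correlated at 0.15 without and 0.21 with the inhibitor. GC content as a source of part of the Dox changes was not tested. Depth in reads is unknown, and the table's 2 decimals limit ratios of genes near 0.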

Other observations

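The contractile and SRF target list, the ATF4 test and the genes of this part were chosen after results were seen. The inhibitor raised several genes of the actin cytoskeleton and of smooth muscle contraction. The myosin light chain gene MYL9 rose from 355 ± 42 to 1260 ± 150 FPKM without Dox (log2 change 1.82) and stood at 1270 ± 87 FPKM with both (2.19 against Dox alone), the vinculin gene VCL rose from 118 to 214 FPKM and the alpha-actinin gene ACTN1 from 161 to 341 FPKM. SRF, the transcription factor that acts on such genes, rose from 20.3 to 37 FPKM, while the calponin gene CNN1 fell from 5.9 to 3.15 FPKM (n = 3 libraries each). Of 17 tested contractile and SRF target genes, 14 rose and 3 fell without Dox (median 0.86) and 14 rose and 1 fell with it (median 1.07), with medians of 0.98 and 1.15 after median-ratio scaling. The list was compiled after several of its genes were seen to rise, so these values do not test a rise of such genes as a class, which cannot be told apart from the choice of genes. YAP/TEAD targets, which share CTGF with other lists, had medians of -0.05 without Dox (7 of 22 rose and 7 fell) and 0.15 with it (10 rose and 4 fell, p = 0.021 with an estimated correlation), so a joint rise of that list in both states was not borne out.

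The ferritin gene FTH1 (chromosome 11, 61959718 to 61967660, minus strand) rose from 3150 ± 330 to 6900 ± 160 FPKM with Dox (1.14) and stood at 2880 ± 170 FPKM with both treatments (interaction -1.35, adjusted p = 9.9e-04). FTL rose from 3570 to 6540 FPKM with Dox (0.87, but -0.16 after quantile normalization) and stood at 1830 FPKM with the inhibitor, though its interaction was not called (-0.54, adjusted p = 0.06). It was called under 7 alternatives, which were median-ratio scaling (-0.58), leaving out DMSO 1 or Dox plus inhibitor 1 (-0.62 each) or replicate 1 of all groups (-0.63), the replicate block (adjusted p = 0.011), and removal of the length and GC trend with or without the block (-0.5 each). After quantile normalization it turned to 0.54 (adjusted p = 0.0023). Ferritin values are uncertain, since both genes have many processed pseudogenes. The heme oxygenase gene HMOX1 rose from 38.4 to 57.6 FPKM with Dox but fell with Dox in the presence of the inhibitor from 51 to 32 FPKM (interaction -1.23, adjusted p = 5.0e-05), and the autophagy receptor gene SQSTM1 rose from 156 to 290 FPKM and stood at 158 FPKM with both (interaction -1.15, adjusted p = 0.0013).

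The YAP/TEAD target gene ANKRD1 rose from 73.1 to 161 FPKM with Dox and stood at 47.4 FPKM with both (interaction -1.03), whereas CTGF moved the other way, from 163 to 87.5 and 243 FPKM (interaction 0.8). Doxycycline acts on mitochondrial ribosomes, and a rise of the ATF4 response that this might cause was not seen, with list medians of -0.07 without and -0.02 with the inhibitor.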
